A study of Sus scrofa with 18 samples.

How the data were processed

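The 18 arrays measured total RNA from LLC-PK1 cells, an epithelial line from pig kidney that was grown past confluence and then treated with all-trans retinoic acid (ATRA), the active form of vitamin A at nuclear retinoic acid receptors. Per the labels, RNA was collected at 0, 0.5, 1, 4, 8 and 12 h of treatment, with 3 biological replicates at each of the 6 time points, and was biotin-labeled and hybridized to Affymetrix porcine arrays. No untreated arrays at the later times exist in the series, so 0 h was the control for every time point and time in culture was not separated from treatment.

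The deposited values are on a log2 scale, with 1 value per probe set and array. They ran from 0.882 to 13.86, array medians from 5.59 to 5.67 and standard deviations from 2.47 to 2.54, so the authors had put the arrays on a common scale. Per the submitters' processing notes, Transcriptome Analysis Console 2.0.0.9 was used; the summarization and normalization method is not given in the sources used here. Values were taken as deposited, with no filter and no offset. The number of arrays limits the precision: the median standard error (SE) of a log2 difference was 0.149 with 3 arrays per time point.

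Of 27558 probe sets, 13323 carried exactly 1 gene symbol, 357 carried several and 13878 carried none. For 12925 of the probe sets with 1 symbol the Entrez identifier was found in the RefSeq gene annotation, and 7 symbols were updated from it. The named probe sets covered 12361 genes, of which 902 had several probe sets; such a gene was represented by the probe set with the highest mean over the 18 arrays. For 1239 probe sets the values on the 18 arrays were identical to those of another probe set, in 602 distinct profiles. The files give no genome positions, so none are stated.

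A linear model with 1 mean per time point was fitted to the 18 arrays with limma 3.58.1 in R 4.3.3, followed by moderated tests (eBayes; 12 residual degrees of freedom, 3.34 prior degrees of freedom). Each later time was compared with 0 h, and the steps from 1 to 4 h, 4 to 8 h and 8 to 12 h were compared as well. A moderated F test asked whether a probe set changed at any time. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over the 27558 probe sets of each comparison, and a probe set was called at an adjusted p under 0.05. Changes are log2 differences from the earlier time with their SE from the model, and n is 3 arrays per time point throughout.

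For gene groups, 38 lists were tested with camera from limma over the 5 comparisons with 0 h, with a preset correlation between genes of 0.01. The 190 tests were adjusted together. Each call was repeated with a correlation estimated from the data for each list, and fry, which tests whether a list's genes move on balance in 1 direction, was run as an alternative. The estimated setting can raise p even where the estimate lies under the preset value. A call lost under it therefore need not reflect correlation between genes. The same lists were tested in the 3 steps between later times, adjusted over those steps. The number of list members passing was counted with p adjusted over all probe sets and with p adjusted over the list alone.

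The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each time, the 10 largest rises and 10 largest falls (12 and 12 at 12 h) among called probe sets with 1 symbol whose 3 values lay wholly above or below the 3 values at 0 h, with each gene entered through its representative probe set alone; chance alone gives such separation for 10% of probe sets with 3 against 3. It also took up to 4 called members of each list per time, the 5 largest rises and falls of each step, and 20 genes of retinoid action and cell junctions whatever their values. Of those 20 genes 11 were measured; the others had no probe set under their symbols and were not analysed here. Some other probe sets of such genes changed more than the last one taken. CXCL2 (probe set 15320856, log2 change 3.16 at 1 h) and TTPA (15279078, 2.72 at 8 h) are examples. A gene outside the rule is said to have been chosen after its values were seen.

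The pipeline was tested on simulated data with the size and spread of this series. In the comparison of 4 h with 0 h over 27558 probe sets, 15 of 67 shifts of 0.5 on the log2 scale were called, 49 of 67 shifts of 1 and 63 of 66 shifts of 2, while 5 of 27358 unchanged probe sets were called. Of 38 simulated lists over 12361 genes, the 1 shifted list was the 1 that was called. The simulation was set to the size and spread of the series, not to the share of probe sets that change. The real comparison at 4 h called 3568, more than were shifted here, and adjusted p depends on that share. The rates of recovery need not hold there. Correlation between genes of a list was not simulated either. In the real data the estimated correlation ran from -0.0286 (fibroblast and mesenchymal markers) to 0.934 (G2/M and mitosis genes). How often the list test calls unchanged lists of correlated genes was therefore not tested. Overlaps between times that share the 0 h arrays were set against 20 simulated data sets in which the called changes of the later time were moved to random probe sets. This comparison was added after seeing the data, and its simulated sets had fewer calls than the real data at most times.

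The labels number the replicates from 1 to 3 without saying what a number shares. The numbers were taken to pair the arrays of a comparison where, for each number, the arrays' deviations from their time means correlated above 0.1 over probe sets. This held for 0.5 h (correlations 0.427, 0.105 and 0.242 for replicates 1 to 3), 1 h (0.417, 0.158 and 0.287), 4 h (0.421, 0.142 and 0.185), 1 to 4 h (0.451, 0.284 and 0.274) and 4 to 8 h (0.507, 0.378 and 0.337). It failed for 8 h (lowest 0.0952), 12 h (0.0505) and 8 to 12 h (-0.00451). Missing the cutoff does not show that arrays were unpaired: at 8 h replicates 1 and 3 correlated at 0.375 and 0.212. The check was not run over the whole course.

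Alternatives were array medians set to 1 value, quantile normalization, leaving out probe sets with a mean under the median, trend and robust moderation, fitting only the 6 arrays compared, array weights, a minimum change of 2-fold, only probe sets with 1 symbol, the replicate number as a block, and leaving out each array in turn. For lists, fry, the mean of a gene's probe sets and the estimated correlation were added, and for named genes each other probe set. After seeing the data, 3 more were added: leaving out the replicate 1 arrays of 0 to 8 h, leaving out the 6 replicate 1 arrays, and counting identical probe sets once. The block was then also run on the lists of the steps between later times and with an estimated correlation, and each list was tested between each pair of later times, 380 tests adjusted together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.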

Results

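Transcript levels were measured in LLC-PK1 cells, a porcine kidney epithelial line with proximal tubule features, before ATRA treatment and after 0.5, 1, 4, 8 and 12 h of it. Each of the 6 time points had 3 arrays from biological replicates, 18 arrays in all, and each array gave a log2 signal for 27558 probe sets. Signals correlated at 0.9817 to 0.9946 between replicates across probe sets. Over all pairs of arrays the range was 0.9721 to 0.9948, so these values hardly set replicates apart from other pairs. The number of arrays limits the precision of each difference.

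Across the whole time course, 4332 probe sets changed by the moderated F test, covering 2371 genes. The number that differed from 0 h was 64 at 0.5 h, 211 at 1 h, 3568 at 4 h, 1681 at 8 h and 728 at 12 h. Of 190 list tests against 0 h, 39 passed with the preset correlation. With an estimated correlation 8 calls held. These were the immediate early genes and the retinoic acid induced genes of other cell types at 0.5 h and 1 h, and the ERK feedback and output, NF-kappaB and cytokine, YAP and SRF target, and fibroblast and mesenchymal lists at 1 h. Under the replicate block with an estimated correlation, which was added after the data were seen, the 2 calls on retinoic acid induced genes were lost (adjusted p = 0.0738 at 0.5 h and 0.0738 at 1 h) and the other 6 held.

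**Figure D1:**
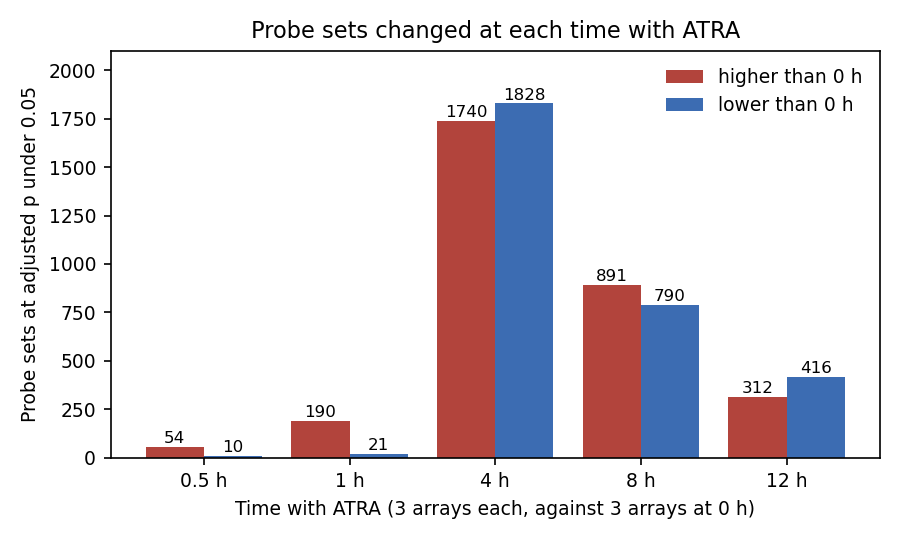
Number of probe sets that differed from 0 h (vertical axis, count at an adjusted p under 0.05) against hours of ATRA treatment (horizontal axis), with 3 arrays per time. Bars side by side, both rising from 0, give the probe sets with higher and with lower signal. The count went from 64 at 0.5 h to 3568 at 4 h and was 728 at 12 h.

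The first question was how genes of retinoid handling changed with ATRA. CYP26A1, the cytochrome P450 that degrades retinoic acid (probe set 15227675), rose 3.08-fold at 1 h (log2 change 1.62 ± 0.15 SE, adjusted p = 2.89e-05), 3.47-fold at 4 h, 4.32-fold at 8 h and 4.79-fold at 12 h (2.26 ± 0.15, adjusted p = 3e-06). DHRS3, a reductase that converts retinaldehyde back to retinol (probe set 15304655), rose 1.98-fold at 1 h, 4.61-fold at 4 h, 7.25-fold at 8 h and 8.91-fold at 12 h (3.16 ± 0.14, adjusted p = 1.15e-08). RARA, a nuclear receptor for retinoic acid, rose 1.40-fold at 4 h (0.49 ± 0.09, adjusted p = 0.00191) and 1.25-fold at 8 h (adjusted p = 0.0426). STRA6, the cell surface receptor for retinol-binding protein, fell 1.57-fold at 12 h (-0.65 ± 0.10, adjusted p = 0.0028). The 8 h call on RARA was lost in 5 of 6 fits without 1 array, with an adjusted p of up to 0.137.

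RARB, RXRA, CRABP2 and TGM2, which many other cell types raise or use in their response to retinoic acid, passed at none of the 5 times. RXRA had a mean log2 signal of 5.27 at 0 h, under the lowest array median of 5.59, which limits what its result can show. RARB, for example, was at 0.847 of its 0 h level at 12 h (adjusted p = 0.641) and TGM2 at 1.01 (adjusted p = 0.976). The retinoid metabolism and transport list, with 19 genes measured, was not called at any of the 5 times; at 12 h 2 members rose, 1 fell and its adjusted p was 0.134, and 2 rose and 1 fell when adjusted over the list alone. Of 15 retinoid receptors and coregulators, 1 rose and 4 fell at 4 h (1 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.292). The list of retinoic acid induced genes of other cell types, 33 measured, was called higher at 0.5 h (adjusted p = 2.7e-06) and 1 h (2.91e-06), and both calls held with an estimated correlation (adjusted p = 0.00919 in each), though not when the replicate block was added to it (0.0738 and 0.0738). The 3 members that rose at 0.5 h were ELF3, an epithelial transcription factor, BTG2, an antiproliferative gene also on the immediate early list, and BHLHE40, a repressor with clock functions, while CYP26A1 had not yet passed (1.45-fold, adjusted p = 0.421). The 0.5 h call on BHLHE40 was lost without replicate 2 of 0 h or replicate 1 of 0.5 h (adjusted p of up to 0.0817). At 1 h 6 members rose, and 7 rose and 2 fell when adjusted over the list alone. At 12 h, 6 rose and 2 fell with a list median of -0.022, a mean of 0.232 and an adjusted p of 0.246, so median and mean differed in sign.

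**Figure D2:**
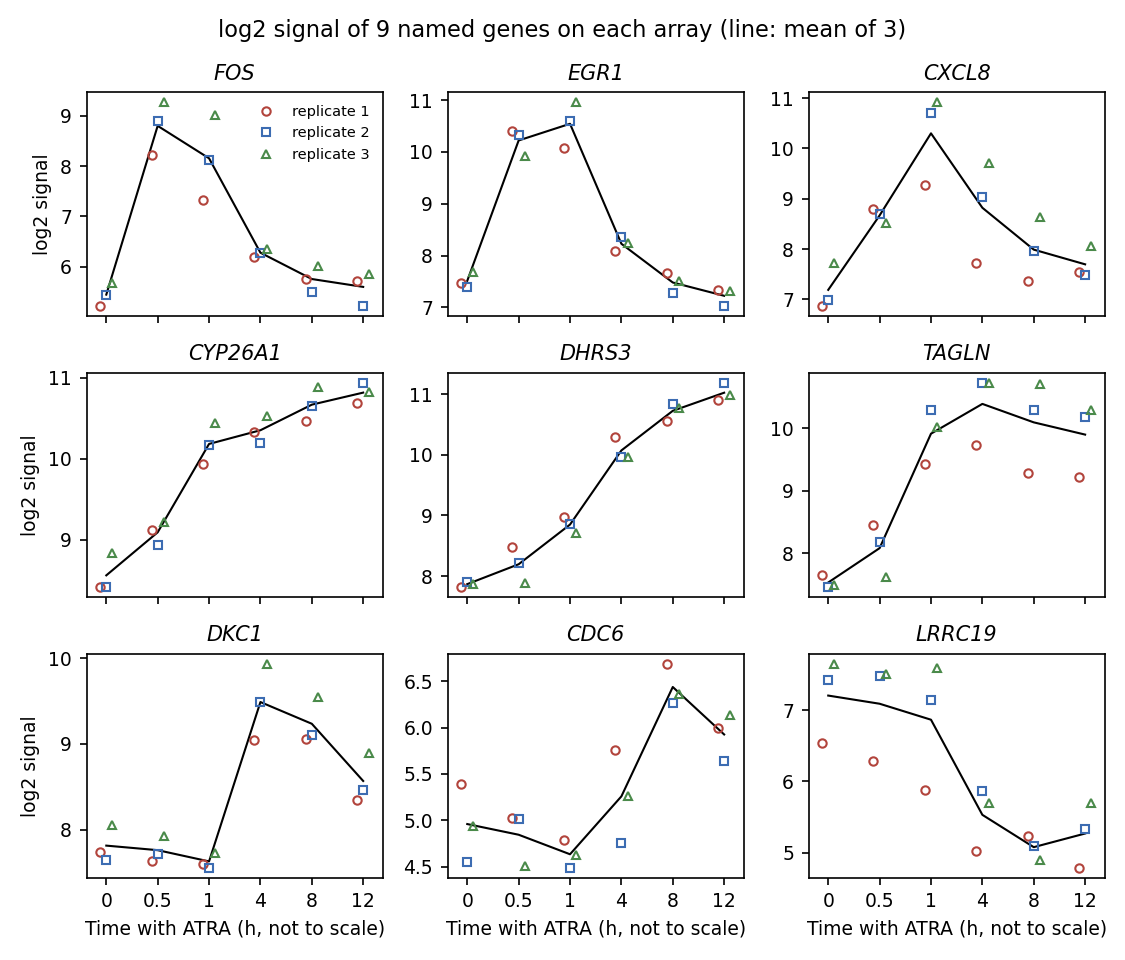
Log2 signal (vertical axis) against hours of ATRA treatment (horizontal axis) for 9 genes, with points for single arrays and lines through the mean of 3 arrays. FOS was 10.2-fold higher at 0.5 h, DKC1 3.19-fold higher at 4 h and DHRS3 8.91-fold higher at 12 h than at 0 h.

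The earliest comparison asked what ATRA treatment changed within 0.5 h. Immediate early genes were among the largest rises: FOS, a subunit of the AP-1 transcription factor, rose 10.2-fold (3.35 ± 0.33, adjusted p = 0.000129, n = 3 arrays per time). The transcription factor EGR1 rose 6.54-fold (2.71 ± 0.19, adjusted p = 3.61e-06), ZFP36, which destabilizes cytokine mRNAs, 6.15-fold (2.62 ± 0.19) and CYR61, a secreted matricellular protein, 5.82-fold (2.54 ± 0.26). DUSP5, a phosphatase of nuclear ERK, rose 3.99-fold (2.00 ± 0.24, adjusted p = 0.000797). In all, 54 probe sets were higher and 10 lower, among them 25 genes higher and 3 lower, and 49 of the rises were at least 2-fold. The ubiquitin ligase gene RNF220 fell 2.24-fold (-1.16 ± 0.19, adjusted p = 0.00886), a call lost in 3 of 6 fits without 1 array (adjusted p of up to 0.0634). The calls on LOC100152864 and LOC100519366, also lower, were lost in 6 of 6 and 5 of 6 such fits (up to 0.312 and 0.19).

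At 0.5 h, 11 of 19 measured immediate early genes rose and none fell, 16 and 0 adjusted over the list alone, with a median log2 change of 1.65 and an adjusted list p of 1.43e-65 (0.00705 with an estimated correlation). Of 18 ERK feedback and output genes 1 rose (4 adjusted over the list alone), of 21 NF-kappaB and cytokine genes 1 rose (6 adjusted over the list alone) and of 16 YAP and SRF target genes 1 rose (4 adjusted over the list alone). These 3 lists were called higher (adjusted p = 2.24e-07, 1.15e-09 and 9.98e-07), but not with an estimated correlation (adjusted p = 0.205, 0.0965 and 0.196). The p53 target list was called higher with 1 of 18 genes higher (3 adjusted over the list alone; adjusted p = 0.007, and 0.366 with an estimated correlation), and the glycolysis and hypoxia list with 2 of 27 by both adjustments (adjusted p = 0.0488, and 0.534 with an estimated correlation). The p53 target that rose was BTG2 and the YAP and SRF target CYR61, both also on the immediate early list. The keratin and squamous differentiation list was called with 0 of 11 genes passing in limma by either adjustment (adjusted p = 0.0472, and 0.503 with an estimated correlation). Without replicate 1 of 0 h the p53 target and keratin lists were not called (adjusted p = 0.115 and 0.352), nor was the glycolysis and hypoxia list without replicate 2 or 3 (0.213 and 0.273). With the replicate number as a block, the glycolysis and hypoxia list was not called (adjusted p = 0.0596), nor was the nuclear receptor NR4A3, which rose 3.44-fold at 0.5 h (adjusted p = 0.0319, and 0.0567 with the block). The NR4A3 call was also lost in 5 of 6 fits without 1 array (adjusted p of up to 0.19). The block called 2 further lists at 0.5 h, the G1/S and DNA replication genes as lower (adjusted p = 0.035) and the fibroblast and mesenchymal markers as higher (0.0345). With the block and an estimated correlation both were lost (adjusted p = 0.625 and 0.182).

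The comparison of 1 h with 0 h asked how the early response went on. CYR61 rose 11.9-fold (3.58 ± 0.26, adjusted p = 9.1e-07), DUSP5 10.4-fold (3.38 ± 0.24) and the stress-induced transcription factor ATF3 9.80-fold (3.29 ± 0.27). Other rises were those of EDN1, the endothelin-1 precursor, 8.64-fold (3.11 ± 0.34), the neutrophil chemokine CXCL8 8.62-fold (3.11 ± 0.48), the cytokine IL6 5.59-fold (2.48 ± 0.38) and the chemokine CCL20 5.48-fold (2.45 ± 0.38). PLAT, the tissue plasminogen activator, rose 5.31-fold (2.41 ± 0.24) and TAGLN, an actin-binding protein of contractile cells, 5.21-fold (2.38 ± 0.38). Among falls, CCNG2, a cyclin of cell cycle arrest, dropped 1.86-fold (-0.90 ± 0.15, adjusted p = 0.00606) and ARRDC3, an arrestin family member, 1.64-fold (-0.71 ± 0.12, adjusted p = 0.00552). Rises numbered 190 probe sets and falls 21, or 96 and 13 genes. The falls were 8 to 17 in fits without 1 array and 7 when only the 6 arrays compared were fitted.

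Of the 54 probe sets higher at 0.5 h, 52 were also higher at 1 h, against 0.372 expected if the calls were independent and at most 1 in simulated data with the 1 h changes moved to random probe sets. Part of the excess may come from the shared 0 h arrays, though the simulated data shared them too and gave a mean of 0.3. Of the 10 lower at 0.5 h, 1 was lower at 1 h, against at most 2 in the simulated data. With the replicate number as a block, 322 probe sets passed at 1 h (268 higher, 54 lower) in place of 211.

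Immediate early genes stayed high at 1 h, with 16 of 19 higher and 0 lower (17 and 1 adjusted over the list alone), a median of 2.29 and an adjusted p of 3.36e-63 (0.00705 with an estimated correlation). The NF-kappaB and cytokine list had 10 of 21 genes higher (12 adjusted over the list alone; adjusted p = 4.87e-25). The ERK feedback and output list had 7 of 18 higher (9; adjusted p = 3.93e-21) and the YAP and SRF target list 6 of 16 (11; adjusted p = 1.38e-24). Examples were SPRY1, an inhibitor of receptor tyrosine kinase signalling (2.86-fold), and the YAP targets CTGF (7.95-fold) and ANKRD1 (7.64-fold). These 3 calls held with an estimated correlation (adjusted p = 0.00705, 0.0187 and 0.00705). The fibroblast and mesenchymal list was called higher (1 of 15 rose, 2 adjusted over the list alone; adjusted p = 0.000277, and 0.0187 with an estimated correlation); its riser was TAGLN, which is also on the YAP and SRF list.

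Extracellular proteases and inhibitors, 22 measured, had 4 genes higher at 1 h by both adjustments, among them PLAT and the urokinase gene PLAU (4.00-fold, adjusted p = 0.00633). This list's median was -0.0134, its mean 0.311 and its test positive (adjusted p = 0.00239), and the call was lost at adjusted p = 0.0572 with an estimated correlation. The estimate was 0.00468, under the preset 0.01, yet the unadjusted camera p went from 0.000339 to 0.00271. A higher correlation thus does not account for that loss. The p53 target list was called higher with 3 genes higher and 1 lower by both adjustments (adjusted p = 0.0018, and 0.311 with an estimated correlation). The G1/S and DNA replication list was called lower, with no single gene of 18 passing in limma by either adjustment, a median of -0.254 and an adjusted p of 0.00229, but 0.462 with an estimated correlation and 0.145 without replicate 1 of 0 h. The block added the WNT signalling targets as higher at 1 h (adjusted p = 0.00741) and the G2/M and mitosis genes as lower (1.95e-05, with 0 of 20 genes passing in limma with the block). Both were lost with the block and an estimated correlation (adjusted p = 0.186 and 0.419).

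The most probe sets differed from 0 h at 4 h, the comparison that asked which transcripts followed the early genes. Of these 1740 were higher and 1828 lower, or 975 and 1055 of 12361 genes. Counts of called list members at 4 h are to be read beside these shares. PLAT reached 10.3-fold (3.36 ± 0.24, adjusted p = 1.69e-06), TAGLN 7.26-fold (2.86 ± 0.38, adjusted p = 0.000164), and SLC34A2, a sodium-phosphate cotransporter, 6.68-fold (2.74 ± 0.17, adjusted p = 9.43e-07). The cytokine receptor genes IL4R and IL1R1 rose 4.84-fold (2.27 ± 0.21) and 4.71-fold (2.24 ± 0.34). KLHL24, an adaptor for ubiquitin ligation, fell 3.18-fold (-1.67 ± 0.19, adjusted p = 6.4e-05), PLCL1, a phospholipase C-like protein without catalytic activity, 3.02-fold (-1.60 ± 0.19) and PTGFR, the prostaglandin F receptor, 2.93-fold (-1.55 ± 0.23). Fewer changes were large, with 310 rises and 180 falls of at least 2-fold.

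Ribosome biogenesis genes rose together at 4 h: 17 of 21 were higher and 0 lower (18 and 0 adjusted over the list alone), with a median log2 change of 1.02 (adjusted p = 1.79e-16, and 0.261 with an estimated correlation). They included DKC1, the pseudouridine synthase of small nucleolar RNPs (3.19-fold, 1.68 ± 0.20), URB2 (2.92-fold, 1.55 ± 0.17) and the rRNA methyltransferase NOP2 (2.83-fold, adjusted p = 4.39e-05). Of 37 cytosolic ribosomal protein genes none passed in limma at any of the 5 times by either adjustment, and that list was not called (4 h median 0.0512, adjusted p = 0.464). Of 25 unfolded protein and integrated stress response genes 10 rose and 0 fell (11 adjusted over the list alone; adjusted p = 0.000171, and 0.247 with an estimated correlation), among them CHAC1, which degrades glutathione (2.23-fold), the asparagine synthetase ASNS (2.20-fold) and the pseudokinase TRIB3 (1.96-fold). Of 15 heat shock genes 6 rose (7 adjusted over the list alone; adjusted p = 0.0176, and 0.47 with an estimated correlation), such as HSPH1 (1.83-fold).

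Of 18 ERK feedback and output genes 8 were higher at 4 h (9 adjusted over the list alone; adjusted p = 1.46e-06, and 0.236 with an estimated correlation). So were 7 of 21 NF-kappaB and cytokine genes (10; adjusted p = 5.54e-05, and 0.261 with an estimated correlation). Of the YAP and SRF target genes 7 of 16 were higher and 1 lower (11 and 1; adjusted p = 1.19e-06, and 0.196 with an estimated correlation). Immediate early genes had 5 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.00499, and 0.653 with an estimated correlation). Examples were SPRED1, an inhibitor of Ras-ERK signalling (2.51-fold, 1.32 ± 0.15), and the focal adhesion gene VCL (2.19-fold, 1.13 ± 0.14).

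Of 26 proximal tubule genes 6 fell and 0 rose (8 and 0 adjusted over the list alone) at 4 h, with a median of -0.294 and an adjusted p of 0.0109, but 0.221 with an estimated correlation. They included SLC34A1, the main phosphate transporter of the proximal tubule (1.85-fold lower, -0.88 ± 0.14), and PCK1, the gluconeogenic enzyme (1.69-fold lower, -0.76 ± 0.17). Of 28 HOX genes 2 rose and 6 fell by both adjustments; HOXA10 fell 2.38-fold (-1.25 ± 0.16), HOXA5 2.10-fold (-1.07 ± 0.12) and HOXA9 2.06-fold (-1.04 ± 0.14), while HOXD1 rose 2.10-fold (1.07 ± 0.15). The HOX list was not called against 0 h at any of the 5 times (4 h adjusted p = 0.32).

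Among 12 measured claudins, which seal or open the tight junction to ions, CLDN8 fell 2.72-fold at 4 h (-1.45 ± 0.19, adjusted p = 0.00015). It was the sole member called at any of the 5 times; adjusted over the list alone, 1 member also passed as higher at 1 h. The 4 h list test gave an adjusted p of 0.977, a median of 0.109 and a mean of -0.0534, which differ in sign. CLDN2, CLDN4 and CLDN7 passed at none of the 5 times; CLDN4 was at 1.51-fold at 1 h (adjusted p = 0.144) and 1.36-fold at 4 h (0.0915), and with the replicate number as a block it passed at both (adjusted p = 0.0116 and 0.0104). CLDN2 was at 0.664 of its 0 h level at 4 h (adjusted p = 0.105). CLDN7 had a mean log2 signal of 3.749 at 0 h, where the lower quartiles of the 0 h arrays were 3.756, 3.795 and 3.747. At so low a level a missing call says little. Of 12 other tight junction genes 2 rose and 4 fell at 4 h (2 and 5 adjusted over the list alone; list adjusted p = 0.445). Of 14 adherens junction and desmosome genes 1 rose and 3 fell at 4 h (1 and 6; list adjusted p = 0.114).

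The number of probe sets called at 4 h was 2113 without replicate 3 of 4 h and 1378 when only the 6 arrays compared were fitted, where rises outnumbered falls (760 against 618). With the replicate number as a block, the interleukin gene IL1A lost its 4 h call (1.91-fold, adjusted p = 0.0481, and 0.0502 with the block), which was also lost in 5 of 6 fits without 1 array (up to 0.247). The block added 4 list calls: WNT signalling targets (adjusted p = 0.0403) and keratin and squamous differentiation genes (0.046) as higher, and G2/M and mitosis (0.000112) and cholesterol synthesis genes (0.0355) as lower. None of these 4 calls held with the block and an estimated correlation (adjusted p = 0.278, 0.35, 0.448 and 0.625).

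**Figure D3:**
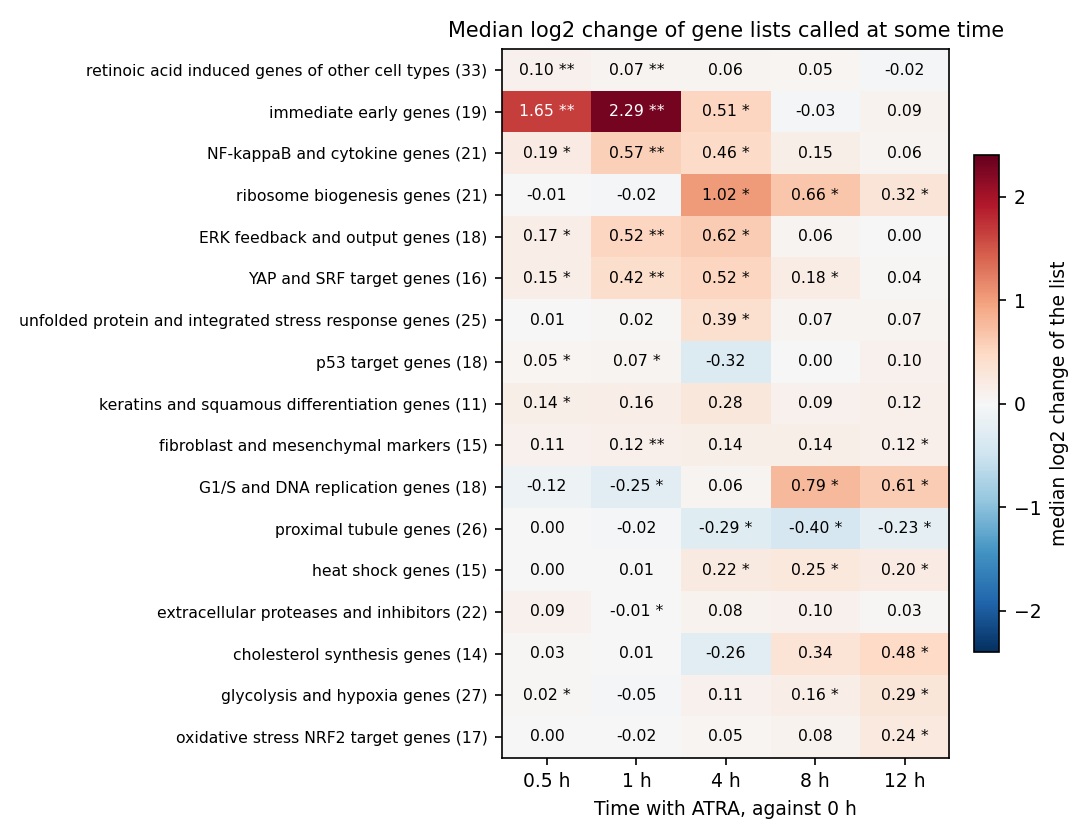
Median log2 change from 0 h of each of 17 gene lists (rows, genes measured in parentheses) at 0.5, 1, 4, 8 and 12 h (columns), for lists called at 1 or more times. A star marks a call with the preset correlation and 2 stars a call that also held with an estimated one; ribosome biogenesis genes stood at 1.02 at 4 h and G1/S and DNA replication genes at 0.785 at 8 h.

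The step from 1 h to 4 h asked directly what changed between the early and the broad response, with 1564 probe sets higher and 1361 lower. SLC34A2 rose 6.25-fold (2.64 ± 0.17, adjusted p = 3.05e-06), IL4R 5.09-fold (2.35 ± 0.21) and DKC1 3.63-fold (1.86 ± 0.20). EGR2 fell 6.92-fold (-2.79 ± 0.39), ATF3 6.87-fold (-2.78 ± 0.27) and EGR1 4.98-fold (-2.32 ± 0.19). Of the immediate early genes 14 of 19 fell (16 adjusted over the list alone; median -1.82, adjusted p = 2.13e-16), and of the ribosome biogenesis genes 18 of 21 rose (19; median 0.956, adjusted p = 1.25e-16). Neither call held, at adjusted p = 0.327 and 0.345 with an estimated correlation. The p53 target and proximal tubule lists were called lower as well (adjusted p = 6.11e-05 and 0.00545), both at adjusted p = 0.327 with an estimated correlation. Called higher were the unfolded protein and integrated stress response list (adjusted p = 0.00084, and 0.351 with an estimated correlation) and the G1/S and DNA replication list (0.0123, and 0.658 with an estimated correlation). The count of 2925 became 1607 without replicate 3 of 4 h and 585 when only the 6 arrays compared were fitted. The NF-kappaB and cytokine list was called lower in this step (adjusted p = 0.0465, and 0.658 with an estimated correlation), but not with the replicate block (0.0684).

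The 8 h comparison asked which changes lasted and which came late, and gave 891 probe sets higher and 790 lower, or 535 and 442 genes. With array medians set to 1 value it gave 1055 higher and 636 lower. Rises included DHRS3, TAGLN (5.91-fold, 2.56 ± 0.38), SLC34A2 (5.32-fold, 2.41 ± 0.17) and PLAT (4.50-fold, 2.17 ± 0.24). P2RY1, a receptor for extracellular ADP, rose 3.98-fold (1.99 ± 0.23, adjusted p = 0.000237) and POLE2, a subunit of DNA polymerase epsilon, 3.15-fold (1.66 ± 0.27, adjusted p = 0.002). LRRC19, a leucine-rich repeat receptor, fell 4.37-fold (-2.13 ± 0.43, adjusted p = 0.00782), PLCL1 3.40-fold (-1.76 ± 0.19) and the flavin monooxygenase FMO5 2.81-fold (-1.49 ± 0.20).

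Of 18 G1/S and DNA replication genes 10 were higher and 0 lower at 8 h (15 and 0 adjusted over the list alone), with a median of 0.785 and an adjusted p of 1.45e-10 (0.158 with an estimated correlation). Examples were CDC6, a licensing factor of replication origins (2.79-fold, 1.48 ± 0.25), the chromatin assembly subunit CHAF1B (2.68-fold, 1.42 ± 0.24) and the helicase subunit MCM4 (2.33-fold, 1.22 ± 0.16). Of the ribosome biogenesis genes 10 of 21 were higher (18 adjusted over the list alone; median 0.663, adjusted p = 6.8e-13, and 0.341 with an estimated correlation). Of 27 glycolysis and hypoxia genes 5 rose (7 adjusted over the list alone; adjusted p = 0.00179), among them HK2, a hexokinase (2.84-fold, 1.51 ± 0.18), and PDK1, which holds pyruvate dehydrogenase inactive (2.03-fold, 1.02 ± 0.21). That call was lost, at adjusted p = 0.353 with an estimated correlation. The heat shock list (4 of 15 rose, and 6 rose and 1 fell adjusted over the list alone) and the YAP and SRF target list (4 of 16 rose, and 6 adjusted over the list alone) were called higher at adjusted p = 0.016 and 0.0109. Both calls were lost, at adjusted p = 0.462 with an estimated correlation, and the heat shock call also without replicate 1 of 0 h (0.0545).

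Of the proximal tubule genes 5 fell and 1 rose at 8 h (7 and 1 adjusted over the list alone), with a median of -0.396 and an adjusted p of 0.000414, but 0.0965 with an estimated correlation. SLC34A1 fell 1.74-fold (-0.80 ± 0.14) and SLC5A2, the main glucose transporter of the early proximal tubule, 1.60-fold (-0.68 ± 0.12). HNF4A, a transcription factor of the proximal tubule, rose 1.61-fold (0.69 ± 0.17, adjusted p = 0.0265, up to 0.109 in the fits without 1 array). Of the probe sets called at 8 h, 573 were higher and 563 lower at 4 h as well, against 56.3 and 52.4 expected if independent and at most 59 and 51 with the 8 h changes moved to random probe sets. Part of the excess may come from the shared 0 h arrays, though the simulated data shared them too and gave means of 43.4 and 40.5. The 8 h count of 1681 was 703 without replicate 2 and 1009 without replicate 3 of 0 h, 892 without replicate 3 of 8 h, and 229 when only the 6 arrays compared were fitted.

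The step from 4 h to 8 h tested which genes turned between these times, with 500 probe sets higher and 411 lower. POLE2 rose 2.92-fold (1.54 ± 0.27, adjusted p = 0.00644), while IL4R fell 3.29-fold (-1.72 ± 0.21, adjusted p = 0.00121) and DUSP5 2.92-fold (-1.55 ± 0.24, adjusted p = 0.00396). Of the G1/S and DNA replication genes 6 of 18 rose (12 adjusted over the list alone; median 0.632, adjusted p = 1.5e-09, and 0.327 with an estimated correlation), and of the ERK feedback and output genes 6 of 18 fell (11; median -0.583, adjusted p = 7.06e-08, and 0.327 with an estimated correlation). The G2/M and mitosis list was called higher with 0 of 20 genes passing in limma by either adjustment (median 0.597, adjusted p = 0.00709, and 0.855 with an estimated correlation). The median deviation of its genes on replicate 1 from the mean of the other 2 arrays was above 0 at each of the 6 times. Fitted with the replicate block, 13 of 20 were higher and the list was called with the preset correlation (adjusted p = 2.69e-13, and 0.223 with an estimated correlation); without the 6 replicate 1 arrays 5 were higher. In this step 13 lists were called. The others called lower were the ribosome biogenesis (adjusted p = 2.8e-05), NF-kappaB and cytokine (2.8e-05), immediate early (6.11e-05), YAP and SRF target (0.000277), stress response (0.00028), protease (0.0172) and WNT target lists (0.0174). They were lost at adjusted p = 0.658, 0.345, 0.645, 0.351, 0.345, 0.327 and 0.345 with an estimated correlation. The others called higher were the cholesterol synthesis (adjusted p = 0.000976), p53 target (0.00247) and HOX lists (0.0155), lost at adjusted p = 0.658, 0.361 and 0.327 with an estimated correlation.

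The 911 probe sets of this step became 2243, 200 and 253 without replicates 1, 2 and 3 of 4 h, and 479 and 383 without replicates 1 and 2 of 8 h. Falls outnumbered rises without replicate 2 of 4 h (76 higher, 124 lower), replicate 3 of 4 h (125 and 128) and replicate 1 of 8 h (203 and 276). With the replicate number as a block 2178 passed (1288 higher, 890 lower), and with only the 6 arrays compared 0 passed.

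At the latest time the question was which changes persisted for 12 h, and 312 probe sets were higher and 416 lower, or 188 and 216 genes. DHRS3, TAGLN (5.16-fold, 2.37 ± 0.38), CYP26A1 and PLAT (4.69-fold, 2.23 ± 0.24) were among the rises. SLC34A2 (3.59-fold, 1.84 ± 0.17), P2RY1 (3.58-fold, 1.84 ± 0.23), SLC51B, a subunit of the basolateral bile acid transporter (3.21-fold, 1.68 ± 0.23), and SLC25A15, the mitochondrial ornithine carrier (3.06-fold, 1.61 ± 0.14), rose as well. PLCL1 fell 3.10-fold (-1.63 ± 0.19), FMO5 2.95-fold (-1.56 ± 0.20) and DMD, the dystrophin gene, 2.76-fold (-1.46 ± 0.24). HNF4A was 2.13-fold higher (1.09 ± 0.17, adjusted p = 0.00306), HOXD1 2.29-fold (1.20 ± 0.15) and HOXB2 1.75-fold (0.81 ± 0.11).

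At 12 h 7 lists were called higher. Glycolysis and hypoxia genes had 5 of 27 members higher (10 adjusted over the list alone; median 0.293, adjusted p = 1.15e-09, and 0.0855 with an estimated correlation), with PDK1 at 2.43-fold, HK2 at 2.22-fold and DDIT4, an inhibitor of mTORC1, at 2.27-fold. G1/S and DNA replication genes had 3 of 18 higher (13 adjusted over the list alone; median 0.607, adjusted p = 1.21e-09, and 0.196 with an estimated correlation), such as MCM4 (2.20-fold, 1.14 ± 0.16). Ribosome biogenesis genes had 1 of 21 higher (3; median 0.315, adjusted p = 2.88e-06, and 0.534 with an estimated correlation). The cholesterol synthesis list was called higher with 0 of 14 genes passing in limma (1 adjusted over the list alone; adjusted p = 0.00119, and 0.578 with an estimated correlation), and the heat shock list with 1 of 15 (2 higher and 1 lower; adjusted p = 0.0102, and 0.455 with an estimated correlation). The fibroblast and mesenchymal list was called with 2 of 15 higher (4; 0.0254) and the NRF2 target list with 0 of 17 in limma by either adjustment (0.0434). Both were lost, at adjusted p = 0.158 and 0.205 with an estimated correlation. The NRF2 target call was also lost without replicate 1 or 2 of 0 h (adjusted p = 0.0665 and 0.0574), and the fibroblast and mesenchymal call without replicate 3 (0.0624).

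Proximal tubule genes remained lower as a list at 12 h, with 3 lower and 1 higher (9 and 1 adjusted over the list alone), a median of -0.229 and an adjusted p of 0.00741, but 0.205 with an estimated correlation. SLC5A2 fell 1.64-fold (-0.71 ± 0.12), and SLC12A1, the salt transporter of the thick ascending limb, was the sole fall among 20 markers of other nephron segments (2.03-fold lower, -1.02 ± 0.15; 1 rose and 1 fell by both adjustments, list adjusted p = 0.887). Of the probe sets called at 12 h, 246 of 312 higher and 325 of 416 lower were called in that direction at 8 h, or 78.8% and 78.1%. If independent, 10.1 and 11.9 would be expected, and data with the 12 h changes moved to random probe sets gave at most 12 and 18. Part of the excess may come from the shared 0 h arrays, though the simulated data shared them too and gave means of 8.15 and 10.2. The count of 728 was 425, 234 and 333 without replicates 1, 2 and 3 of 0 h and 323, 339 and 259 without those of 12 h, and with array medians set to 1 value rises outnumbered falls, 366 against 339. They did so too without the 6 replicate 1 arrays, 391 against 337.

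The step from 8 h to 12 h asked whether any transcript was still moving. In limma 0 probe sets passed, with a smallest adjusted p of 0.185 and 1608 at an unadjusted p under 0.05; without dim probe sets 3 passed, and with array weights 12. As a list, ribosome biogenesis genes were lower at 12 h than at 8 h (0 of 21 called, 3 adjusted over the list alone; median -0.342, adjusted p = 3.15e-09, and 0.568 with an estimated correlation). Glycolysis and hypoxia genes were higher (0 of 27 called in limma by either adjustment; median 0.117, adjusted p = 0.00247, and 0.45 with an estimated correlation). Of the 4 other calls in this step, the YAP and SRF target (adjusted p = 0.00709) and G1/S and DNA replication lists (0.0323) were lower, but at adjusted p = 0.568 and 0.696 with an estimated correlation. The mitochondrial respiratory chain (adjusted p = 0.0192) and HOX lists (0.0214) were higher, but at adjusted p = 0.696 and 0.345 with an estimated correlation.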

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

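The 7 tests of technical or other explanations in this part were chosen after the results were seen; the tests of differences between times and the splits of the arrays followed rules set before, apart from the adjustment over 380 list tests.

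Changes from 0 h in opposite directions at different times drew attention to 1 gene and 1 list, and the difference itself was tested with limma. ID2, an inhibitor of basic helix-loop-helix transcription factors, rose 1.87-fold at 0.5 h and 1.92-fold at 1 h and fell 1.44-fold at 8 h and 1.57-fold at 12 h. Its log2 signal at 8 h was -1.42 relative to 0.5 h (adjusted p = 4.26e-05) and -1.47 relative to 1 h (1.83e-05). At 12 h it was -1.55 relative to 0.5 h (1.94e-05) and -1.59 relative to 1 h (6.77e-06), each with an SE of 0.139. These pairs were picked because ID2 had opposite calls there, and p was adjusted over probe sets within each pair alone. The falls from 0 h were lost in 5 of 6 fits at 8 h and 6 of 6 at 12 h without 1 array (adjusted p of up to 0.129 and 0.0846). The 0.5 h rise was lost without replicate 2 of 0 h (0.0601). The G1/S and DNA replication list was called lower at 1 h and higher at 8 h and 12 h. These 3 calls against 0 h were lost, at adjusted p = 0.462, 0.158 and 0.196 with an estimated correlation, and the 1 h call also without replicate 1 of 0 h (0.145). Its median log2 difference was 1.03 between 8 h and 1 h and 0.739 between 12 h and 1 h. These pairs of times were picked by the opposite calls, so the differences were adjusted over 380 tests, each list between each pair of later times. They passed with the preset correlation (adjusted p = 9.34e-15 and 3.42e-14) but not with an estimated correlation (adjusted p = 0.174 in each), so the turn stays open.

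G2/M and mitosis genes were higher on the replicate 1 arrays: 20 of 20 lay above the mean of the other 2 arrays at each of the 6 times, with median log2 deviations of 1.23, 1.17, 1.26, 1.57, 1.25 and 0.877 in order of time. A compressed signal range on these arrays would move other genes of like level as much, but against 10000 random lists of matched level the list stood at percentile 100 on each of the 6 arrays. Cells of another type would raise their markers. The highest percentile among the fibroblast, leukocyte and endothelial, and other nephron lists was 77.4, with members of these lists going both ways (medians 0.0341, -0.0532 and -0.0641, SD over members 0.291, 0.119 and 0.207), so this stays open. More dividing cells in these cultures is a candidate explanation: the G1/S and DNA replication list, with a median of 0.295, was at percentile 100 too. Cholesterol synthesis genes, with a median of 0.39, were also at percentile 100, and immediate early and ribosome biogenesis genes at 0. The percentile alone thus does not single out cell division. More dividing cells is a hypothesis, since the labels give no difference between replicates, and what set these cultures apart stays open.

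Immediate early genes were higher at 0.5 h and 1 h. Scaling of the arrays was argued against by the array medians, 5.59 to 5.67, a range that is small beside the list's median change at 0.5 h. That change was 1.65 after quantile normalization. On arrays already so alike this step could hardly have come out otherwise, so it adds little. Handling of the cultures when ATRA was added cannot be told apart from ATRA itself: the list's median was 0.0875 at 12 h, which both would allow, and no culture was handled without ATRA at the later times. Either could therefore account for these early rises, which no value in these data decides.

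The most probe sets changed at 4 h. A shift in the signal range of the 4 h arrays was argued against by the 3625 probe sets that passed after quantile normalization. A single 4 h array was argued against as well, since the lowest count without 1 of them was 2113 (without replicate 3), above the 1681 of 8 h. A broad change in the cells at that time remains a hypothesis that may also reflect time in culture, for which no arrays exist.

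Between 2 time points, the 6 arrays can be split into 3 and 3 in 10 ways, so a share under 0.05 cannot be reached, and the real split was 1 of them. The real count and the highest of the other splits were 64 and 1 at 0.5 h, 211 and 0 at 1 h, 3568 and 0 at 4 h, and 1681 and 0 at 8 h. They were 728 and 0 at 12 h, and 2925 and 1 between 1 h and 4 h. Between 4 h and 8 h they were 911 and 593, the latter in the split that put replicate 1 of 4 h with replicates 1 and 2 of 8 h. Among the 4 splits that part 3 pairs of equal number, the highest other was 0, and with the replicate number as a block the real split gave 2178. Between 8 h and 12 h the 10 splits gave 0 in limma each, the real one included, with 1608 at an unadjusted p under 0.05 in the real one. For the F test over the 18 arrays, the real grouping gave 4332 probe sets and the others of 100 groupings at most 712. The share of 1 in 100 is the lowest these groupings allow, and the random ones did not keep the replicate numbers. Chance is thus argued against there but not excluded.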

How the results depend on the processing

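Leaving out the replicate 1 arrays, counting identical probe sets once, and the block on steps or with an estimated correlation were chosen after the data were seen; the other alternatives were chosen before. No called list and no called named gene result changed direction under the alternatives run on it. Lists that were not called did, such as 9 with fry and 22 without replicate 1 of 0 h. Direction was not followed for named gene results called in neither the main fit nor the alternative. The causes of the changes were not tested unless stated. With medians set to 1 value, quantile normalization, trend and robust moderation, and identical probe sets counted once, each count of probe sets stayed within 1.5 times its value. The balance of rises and falls turned under several alternatives: at 12 h with medians set to 1 value (366 and 339) and without replicate 1 arrays (695 and 690 for 0 to 8 h, 391 and 337 for the 6), at 4 h with only the 6 arrays compared, 2-fold (310 and 180) and in 5 fits without 1 array, at 8 h with array weights (1977 and 2059) and without replicate 1 of 8 h, and in the steps from 1 to 4 h and 4 to 8 h in some fits. Without dim probe sets 1250 passed at 12 h, 1484 between 4 h and 8 h and 3 between 8 h and 12 h. With only the 6 arrays compared, which leaves fewer degrees of freedom, 1378 passed at 4 h, 229 at 8 h, 585 between 1 h and 4 h and 0 between 4 h and 8 h (4542 at an unadjusted p under 0.05 in the limma fit to the 18 arrays). Array weights gave 156 at 0.5 h, 394 at 1 h, 4036 at 8 h, 2462 at 12 h, 2566 between 4 h and 8 h, 12 between 8 h and 12 h and 7511 at any time. Requiring a 2-fold change, a stricter criterion, left 490 at 4 h, 175 at 8 h, 125 at 12 h, 376 between 1 h and 4 h, 108 between 4 h and 8 h and 760 at any time. Testing only probe sets with 1 symbol, which are fewer, gave 34 at 0.5 h and 132 at 1 h. Leaving out the replicate 1 arrays of 0 to 8 h gave 5363 at 4 h, 1385 at 12 h and 2049 between 4 h and 8 h. Leaving out the 6 replicate 1 arrays gave 1841 between 4 h and 8 h. Without 1 array at a time, counts ranged from 43 to 55 at 0.5 h, 150 to 197 at 1 h, and 2113 (without replicate 3 of 4 h) to 4644 at 4 h. At 8 h they ranged from 703 (without replicate 2 of 0 h; 1009 without its replicate 3 and 892 without replicate 3 of 8 h) to 1825, and between 1 h and 4 h from 1607 (without replicate 3 of 4 h) to 3816. They were 0 between 8 h and 12 h in each limma fit and ran from 3204 to 5251 at any time. At 12 h they ranged from 234 to 425, without replicates 2 and 1 of 0 h (333 without replicate 3, and 323, 339 and 259 without replicates 1, 2 and 3 of 12 h). Between 4 h and 8 h they ranged from 200 to 2243, without replicates 2 and 1 of 4 h (253 without replicate 3, and 479 and 383 without replicates 1 and 2 of 8 h).

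With the replicate number as a block, 322 passed at 1 h, 5277 at 4 h, 4368 between 1 h and 4 h and 2178 between 4 h and 8 h. Beside the calls given with the comparisons, it changed no other call on a named gene or on a list against 0 h where the pairing check was met. The lists called in the 3 steps were 31 in place of 26. Beside the NF-kappaB and cytokine loss, cholesterol synthesis genes were added as lower from 1 to 4 h (adjusted p = 0.0103, preset correlation). Glycolysis and hypoxia genes were added as higher from 4 to 8 h (0.0414). Added as higher from 8 to 12 h were G2/M and mitosis (9.43e-05), cholesterol synthesis (0.00319), ribosomal protein (0.0454) and NRF2 target genes (0.0493). Without the block no step call held with an estimated correlation. The pairing check was missed at 8 h, 12 h and between 8 h and 12 h, which leaves pairing there undecided, and was not run over the whole course. With the block, 3191 passed at 8 h, 1943 at 12 h, 6878 over the whole course and 0 between 8 h and 12 h in limma as before. The block added list calls on G2/M and mitosis genes at 8 h and 12 h (adjusted p = 0.00741 and 6.62e-09) and cholesterol synthesis genes at 8 h (0.00924). It lost fibroblast and mesenchymal markers at 12 h (0.0804). The 3 added calls were lost with the block and an estimated correlation (adjusted p = 0.625, 0.28 and 0.543), under which 6 list calls held. The data hint at pairing, though the design does not state it. For 16 of 18 arrays, deviations from the time mean correlated most, on average, with those of arrays of their own number at other times. Of the 39 list calls, the estimated correlation kept 8, fry 30, the filter on dim probe sets 34, the mean of a gene's probe sets 38, quantile normalization 37, the block 37, and leaving out 1 array of 0 h 34 to 37, with 39 to 46 calls in total. Of 359 calls on named genes, 145 were lost with only the 6 arrays compared, 2 with the block and 130 in at least 1 fit without 1 array. Arrays limit what can be seen near background, and the files hold no detection calls.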

Other observations

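The values of TTPA and of the lists on the replicate 1 arrays were examined after the data were seen; the lists themselves were fixed before.

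Several signalling and regulatory lists held single genes that rose or fell at times when the list itself was not called against 0 h. Over all 12361 genes, 975 rose and 1055 fell at 4 h, so a few called members at that time do not set a list apart. HBEGF, a ligand of the EGF receptor, rose 2.44-fold at 0.5 h and 5.44-fold at 1 h (log2 change 2.44 ± 0.16, adjusted p = 3.78e-07), and the receptor gene ERBB2 fell at 4 h (-0.90, adjusted p = 0.000998). Of 14 genes in the EGF receptor family list 1 rose and 4 fell at 4 h (2 and 4 adjusted over the list alone; list adjusted p = 0.633). Of 16 circadian clock genes 5 rose and 3 fell at 4 h by both adjustments (list adjusted p = 0.783), with PER2 higher (1.13, adjusted p = 0.00612) and DBP lower (-0.79, 0.029). Of 25 interferon response genes 4 rose and 2 fell at 4 h (6 and 2 adjusted over the list alone; list adjusted p = 0.575), GBP1 being higher by 1.64 (0.000608) and STAT2 lower (-0.61, 0.0009). Of 23 TGF-beta and BMP signalling genes 3 rose at 1 h by both adjustments (list adjusted p = 0.217), among them SMAD6 (0.68, 0.00793). Of 14 WNT signalling targets 4 rose and 1 fell at 4 h by both adjustments (list adjusted p = 0.088), LEF1 by 0.93 (5.32e-05). Of 14 NOTCH pathway genes 1 rose at 4 h, JAG2 (0.46, 0.0392), with 0 over the list alone (list adjusted p = 0.133). Calls lost in fits without 1 array were those on DBP (3 of 6 fits, adjusted p of up to 0.141), JAG2 (5 of 6, 0.13) and SMAD6 (1 of 6, without replicate 2 of 0 h, 0.0576). The p53 target list had 3 genes higher and 5 lower at 4 h (4 and 9 adjusted over the list alone; list adjusted p = 0.1), with BBC3 lower (-0.93, 0.00109) and PLK3 higher (1.01, 0.000504).

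The cholesterol exporter ABCA1 fell at 4 h (-0.90, adjusted p = 0.000753) in a list of 16 fatty acid synthesis and LXR target genes with 2 higher and 2 lower (3 and 2 adjusted over the list alone; list adjusted p = 0.961). PDK4 fell at 4 h (-1.15, 0.00499) among 23 fatty acid oxidation and PPAR target genes with 1 higher and 3 lower by both adjustments (list adjusted p = 0.133). Of 30 mitochondrial respiratory chain genes 0 passed in limma at any of the 5 times by either adjustment (4 h list adjusted p = 0.674). Of 16 extracellular matrix and basement membrane genes 1 rose and 1 fell at 4 h by both adjustments (list adjusted p = 0.977). Of 8 cell polarity genes PARD6B rose at 1 h (0.65, 0.00207) and MPP5 fell at 4 h (-0.52, 0.00334; list adjusted p = 0.217 and 0.895). KRT19, a simple epithelial keratin, was 1.62-fold higher at 12 h (0.69 ± 0.10, adjusted p = 0.00153), with 2 of 11 keratin and squamous differentiation genes higher by both adjustments (list adjusted p = 0.0745). Of 16 leukocyte and endothelial markers FLT1 passed, at 4 h (0.68, 0.00684) and 8 h (0.58, 0.0318); the list's adjusted p was 0.73 and 0.947. The 8 h call on FLT1 was lost in 5 of 6 fits without 1 array (adjusted p of up to 0.137).

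TTPA, the alpha-tocopherol transfer protein, was chosen after its values were seen because its 2 probe sets differed. Probe set 15279078 went from a log2 signal of 4.39 at 0 h to 7.45 at 12 h (3.06 ± 0.38, 8.35-fold, adjusted p = 0.000478), while probe set 15279082, at 11.29 at 0 h, differed by 0.01 ± 0.07 (adjusted p = 0.97). Of the 902 genes with several probe sets, 46 had a call at 12 h and 22 had each of their probe sets called, with 0 called in opposite directions in limma.

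On the replicate 1 arrays, cholesterol synthesis genes had a median log2 deviation of 0.39 from the mean of the other 2 arrays, interferon response genes of 0.16, immediate early genes of -0.387 and ribosome biogenesis genes of -0.261. CENPF, a kinetochore protein, deviated by 1.62 on average (1.32 to 1.96 over the 6 arrays) and TTK, a spindle checkpoint kinase, by 1.55. With the replicate number as a block, 11 of 20 G2/M and mitosis genes were lower at 4 h (median -0.386), 11 higher at 12 h (median 0.47) and 13 higher at 8 h than at 4 h (median 0.597), where limma without the block called 0 in each. Without the 6 replicate 1 arrays, 1 was lower at 4 h, 0 higher at 12 h in limma and 5 higher at 8 h than at 4 h.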
